A study of Triticum aestivum with 4 samples.

How the data were processed

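RNA of wheat flag leaves (cultivar TAM 107) was measured on 4 single-colour Affymetrix wheat arrays, 2 from control plants and 2 from plants held for 1 h at 40 °C. Per the labels' protocols, potted plants were moved to a growth chamber about 10 days after pollination for the heat treatment, total RNA was extracted with Trizol and biotin-labelled cRNA was made by in vitro transcription. The labels do not say whether control plants were also moved to a chamber, so the move and the temperature cannot be separated. They also do not say whether the 2 replicates of a group came from separate plants, so the p-values measure the spread between these arrays, which may be technical.

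The deposited values are linear MAS5 signal intensities, 1 per probe set and array. The submitters' processing notes name Affymetrix Expression Console 1.1 and MAS5; their settings are not given in the sources used here. The intensities deposited by the authors have a trimmed mean (lowest and highest 2% dropped) of 500.1 on each array, as values scaled to a common target do. Under such scaling, transcripts that rise within the range that enters the mean can push the values of all others down. The highest 2% of values do not enter it. Detection calls were not used here, so a dim probe set cannot be called absent. Gene length, read depth and counting intervals do not apply to arrays; the number of arrays limits the precision.

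The table holds 61290 probe sets, of which 111 are AFFX controls and were left out. The other 61179 include 64 reporter-gene controls whose names lack the AFFX prefix. This was noticed after the results were seen; 3 of them passed the brightness filter, 1 was called higher, and the fit was kept as planned, with a fit without them as an alternative. Log2 of the deposited intensity was analysed with no further normalization. The 30590 probe sets with a mean log2 signal over the 4 arrays of at least 6.11 (the median over the 61179, a signal of 69.1) were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), heat minus control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design has 2 residual degrees of freedom, and limma added 5.45 prior degrees of freedom. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so single values were tested only through this fit across probe sets. Arrays were simulated for the heat versus control comparison with the real control means, and with normal noise whose spread was drawn from limma's fitted prior. Over 30590 probe sets with 200 changed ones inserted, the fit recovered 20.9% of 1.5-fold, 38.8% of 2-fold and 59.1% of 4-fold changes. It made 2 false calls among 81, and 0 calls with nothing changed. The noise followed the fit's own model and far fewer probe sets were changed than were called in the data. These rates therefore check the fit and do not describe the real comparison.

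Gene names came from the platform annotation supplied with the values, which is old and sparse. Of the 61179 probe sets it gives 1 gene symbol to 1273, several to 0 and none to 59906. These 1273 probe sets stand for 771 genes, of which 770 gene IDs were found in the RefSeq gene table of the IWGSC CS RefSeq v2.1 assembly. Nearly all symbols are LOC numbers. A name beyond the number (a symbol or a synonym in the gene table) was available for 102 genes, and 71 of them had a tested probe set. A gene with several probe sets is represented by the one with the highest mean signal. Genes with only a LOC number are unnamed here, and no coordinates are given, because no genome build is tied to the array values. Wheat is hexaploid and its gene copies are nearly identical, so a probe set can report several copies of a gene together, and names ending in _s_at, _x_at or _a_at mark probe sets that can match several transcripts.

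Before the data were examined, 28 gene lists were written as patterns on symbols and synonyms, with seed storage and floral genes as markers of other organs. The patterns for symbols were also applied to synonyms, a reading settled after the name table was seen. Of the lists, 10 had no named gene on the array, 2 had named genes but none bright enough to test (dehydrins, LEA and cold-regulated proteins, with 2 genes, and abscisic acid, gibberellin, ethylene and auxin genes, with 3), and 16 had at least 1 tested gene. The 10 lists without a named gene were HSP70, HSP90, HSP100 and HSP60 chaperones, heat shock transcription factors, endoplasmic reticulum stress, DREB, CBF and ERF factors, WRKY, NAC, MYB and bZIP factors, floral and MADS-box genes, circadian clock genes, calcium and protein kinase signalling, nitrogen metabolism, and metallothioneins. Only 1 list reached the 5 tested genes set for a set test (camera with a preset correlation of 0.01). The genes named in the text are the 12 named genes with the largest rise and the 12 with the largest fall among those past the threshold with no overlap between groups, plus up to 4 genes per list with the smallest unadjusted p, 45 in all.

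The alternatives fixed in advance were quantile, median and cyclic loess normalization, offsets of 16 and 64 before log2, no filter and a stricter filter, eBayes without the trend and with robust estimation, leaving out shared probe sets, the replicate number as a block, unmoderated t statistics and leaving out each array. Scaling on the polyA spike controls, leaving out the reporter controls, unmoderated t statistics for the named genes and other scalings of the control probe sets were added after the data were seen. The replicate numbers were not used in the comparison.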

Results

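The flag leaf, the uppermost leaf of the wheat plant and a main source of assimilate for the filling grain, was profiled after a short heat treatment to ask how its transcripts respond to heat. There were 2 control arrays and 2 arrays from plants kept for 1 h at 40 °C. The median signal was 82.5 and 78.9 on the control arrays and 76.9 and 71.9 on the heat arrays. Over the tested probe sets, log2 signals correlated at r = 0.979 between the control arrays and r = 0.977 between the heat arrays, against 0.914 to 0.915 between groups. These correlations run across probe sets, which are not independent replicates. The median SD between replicates was 0.10 (control) and 0.12 (heat) on the log2 scale, and the median absolute difference between groups was 0.39.

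The largest rise among genes with a name was that of hsp16.9A, a small heat shock protein of the kind that keeps unfolding proteins from aggregating. Its signal went from 193 ± 5.45 to 19394 ± 178 (SD, n = 2 per group), a 100-fold rise (log2 6.65 ± 0.07 SE, adjusted p = 4.99e-09 in limma). FKBP70, a peptidyl-prolyl isomerase that assists protein folding, was already bright in control leaves at 6004 ± 33.8 and reached 41432 ± 504 (SD, n = 2), a 6.90-fold rise (adjusted p = 2.02e-08, limma). The largest fall among genes with a name was that of Hmgb3, a high mobility group protein that binds chromatin. Its signal went from 7931 ± 245 to 2205 ± 222 (SD, n = 2), at log2 -1.85 ± 0.08 SE (adjusted p = 1.91e-06 in limma). Of the 6 tested members of the cytoskeleton and cell wall list, 4 fell, all of them beta-tubulins.

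Across the array, signals of 4339 probe sets were higher and those of 6993 were lower in heat, 37.0% of the 30590 tested (limma, adjusted p below 0.05). In each of these the values of both heat arrays lay on one side of both control arrays. With 2 arrays per group a call at this threshold already requires that, so it adds no support to the calls. Such separation held for 69.1% of all tested probe sets, where chance gives 33.3%. With a change of at least 2-fold, 1682 were higher and 2111 lower, a balance that turned under quantile normalization (1936 higher, 1630 lower), median centring (2055 and 1705) and cyclic loess (2051 and 1468) and was near even with spike scaling (1881 and 1872). It also turned without control replicate 1 (1736 and 1514) or control replicate 2 (1635 and 1538), with the stricter filter (1123 and 904), with an offset of 64 (1381 and 1308) and with unmoderated t statistics (820 and 544). At 4-fold or more 548 rose and 290 fell, at 16-fold or more 112 rose and 17 fell, and at 32-fold or more 66 rose and 2 fell. The 2 that fell, singled out after their values were seen, are probe sets with no gene name, at log2 -6.84 and -5.88. Their heat means were 26.2 ± 12.8 and 16.6 ± 9.59 (SD, n = 2), below the filter signal of 69.1. The 2 largest rises past the threshold (log2 8.25 and 7.82) had control means of 13.8 ± 6.47 and 40.5 ± 52.9 (SD, n = 2), also below it. The sizes of these 4 changes are therefore uncertain. Probe sets that rose at least 2-fold held 4.47% and 4.45% of the summed signal on the control arrays and 16.3% and 16.5% on the heat arrays. This sum includes the highest 2% of values, which the trimmed mean leaves out. The median log2 fold change over all tested probe sets was -0.15. Over 5 classes of brightness it ranged from -0.24 (signals of 123 to 247) to -0.027 (the brightest, 1652 to 55380). Changes of single genes are to be read against the median at their own brightness. Median centring moved the median over all tested probe sets to -0.03 and cyclic loess to -0.02, and centring brought the split to 5033 higher and 4958 lower.

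**Figure D1:**
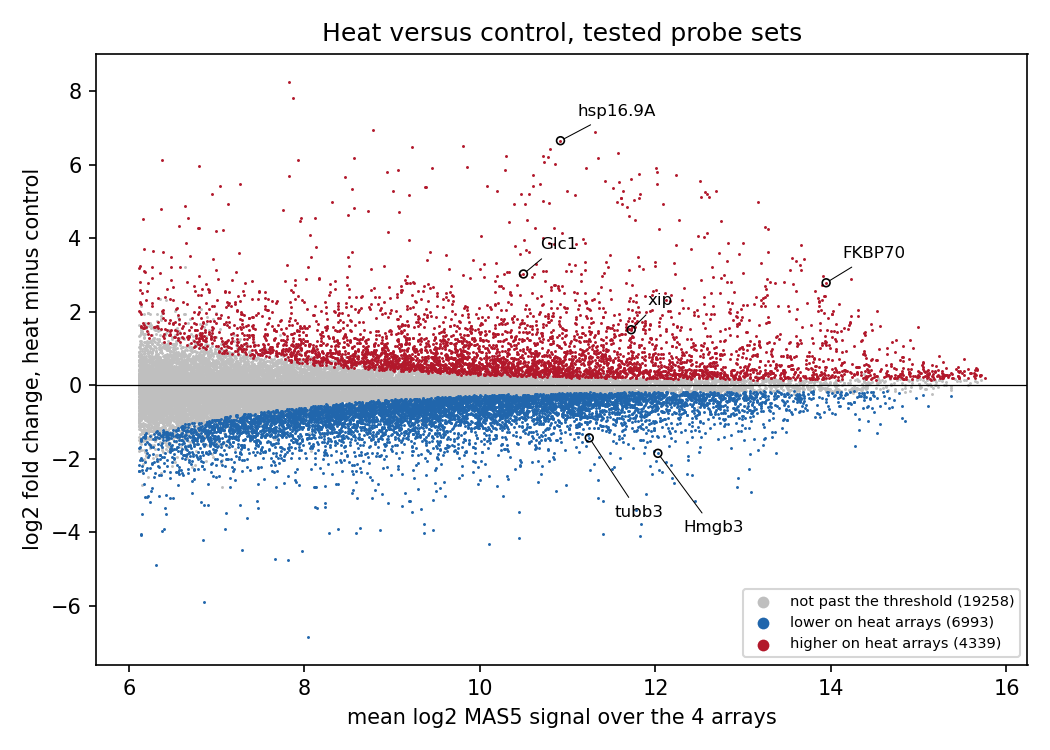
Each point is a tested probe set, with its mean log2 MAS5 signal over the 4 arrays on the x axis and its log2 fold change (heat minus control) on the y axis; red points (4339) were higher and blue points (6993) lower on the heat arrays at an adjusted p below 0.05, grey points did not pass, and black circles mark 6 named genes. Changes of 16-fold or more are mostly rises (112 against 17), and hsp16.9A lies at 6.65. The highest and lowest called points lie at 8.25 and -6.84. Their sizes are uncertain, because the control mean of the highest and the heat mean of the lowest lie below the filter signal.

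**Figure D2:**
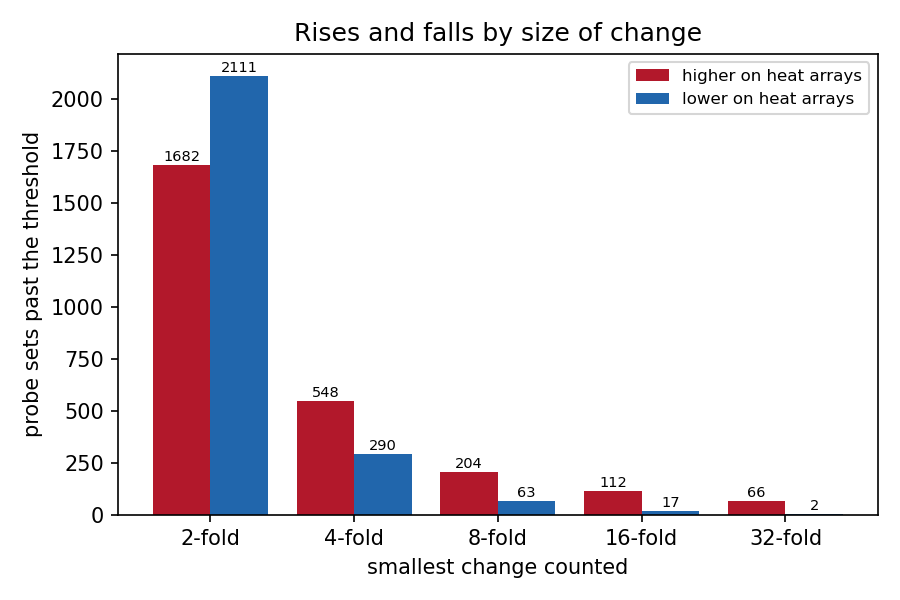
Bars give the number of probe sets past the threshold (y axis, from 0) that rose (red) or fell (blue) by at least the fold on the x axis. On the deposited scaling falls outnumber rises at 2-fold (2111 against 1682), which turned under quantile normalization, median centring and cyclic loess, and rises outnumber falls from 4-fold upward.

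Among the 71 tested genes with a name, 24 rose, 17 fell and 30 did not pass the threshold. In every gene list below, the counts over all tested probe sets were the same when adjusted over the list alone. hsp16.9A was the only tested small heat shock protein with a name, and FKBP70 the only tested co-chaperone. Outside the lists, Glc1 rose 8.14-fold, from 506 ± 29.3 to 4129 ± 361 (SD, n = 2). The xylanase inhibitor xip, a protein that blocks cell wall degrading enzymes of microbes, rose 2.85-fold on one probe set and in the same direction on its second. PEAMT1, phosphoethanolamine methyltransferase on the route to choline, rose 1.67-fold (log2 0.74 ± 0.10 SE), and TaTPC1, a two-pore cation channel, rose 1.44-fold (0.53 ± 0.07). The call of PEAMT1 was lost with unmoderated t statistics, and those of hsp16.9A, FKBP70, Glc1, xip and TaTPC1 held under each alternative that gave them a value. DMAS1, deoxymugineic acid synthase of the iron-chelating phytosiderophore pathway, rose 1.42-fold (0.50 ± 0.11) on 1 of its 3 tested probe sets. The DMAS1 call was lost without control replicate 1 (log2 0.47), and without shared probe sets the gene stood at -0.23.

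In carbohydrate and lipid lists the calls were small rises. The fructan exohydrolase 1-FEH, which breaks down stored fructan, rose 1.31-fold, and 6-FEH stood at log2 0.54 ± 0.45 SE (adjusted p = 0.389, limma), so 1 of the 2 tested members of the sucrose, fructan and raffinose list rose. AGP-S, the small subunit of ADP-glucose pyrophosphorylase and the only tested member of the starch list, rose 1.26-fold. LTP3, a lipid transfer protein and the only tested member of the lipid list, rose 1.29-fold. Under quantile normalization 1-FEH (log2 0.18) and LTP3 (0.05) lost their calls, and LTP3 also without shared probe sets, where its second probe set stands for it (0.22).

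Both tested members of the photosystem list rose, oxygen-evolving proteins of photosystem II. PsbO (OEE1) rose 1.28-fold, and PsbP (OEE2) rose 1.27-fold, but PsbP did not pass under quantile normalization (log2 0.07) or cyclic loess (0.09). PsbO kept its call there at log2 0.10 and 0.13. The highest signal of any probe set, controls included, was 52311 and 52772 on the control arrays and 62439 and 62032 on the heat arrays. Among other named genes of like brightness, CAT1 stood at log2 0.28, PRK at 0.15 and Trx-M at -0.08. A rise particular to photosystem genes therefore cannot be read from these values. In the Rubisco and Calvin cycle list, the brightest probe set of rbcL, the large subunit of Rubisco, rose 1.64-fold to 59912 ± 1744 (SD, n = 2). Of the 12 tested probe sets assigned to rbcL, however, 2 rose and 7 fell, and without shared probe sets the gene stood at log2 -0.67. Phosphoribulokinase (PRK), the other member, was at log2 0.15 ± 0.07 SE (adjusted p = 0.132, limma); its sign turned under quantile normalization (-0.12) and cyclic loess (-0.10), and it passed without control replicate 2 (0.22). Outside the list, FBP, a fructose-1,6-bisphosphatase, fell 1.31-fold and GAPN, the non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, fell 1.32-fold.

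The beta-tubulins that fell, subunits of microtubules, were tubb3 (2.69-fold, from 3987 to 1480), Tubb5 (2.01-fold, with 2 of its 4 probe sets lower), tubb1 (1.45-fold) and Tubb4 (1.28-fold). The probe sets that stand for tubb3, Tubb5 and Tubb4 can match several transcripts, so these may not be falls of 4 separate genes. Of the other 2 members of the cytoskeleton and cell wall list, named after their values were seen, the profilin PRO1 rose (log2 0.21; its direction held under 3 and its call under 1 of the 4 other scalings) and tubb2 was at 0.27 ± 0.28 SE. The list's median log2 fold change was -0.44, and as a set it did not pass limma's camera (adjusted p = 0.13 with 1 list in the family, and adjusted p = 0.281 with an estimated correlation). Calls were lost for Tubb5 without shared probe sets (log2 -0.22), for Tubb4 with median centring (-0.24) and for tubb1 without control replicate 1 (-0.43). Outside the list, the tubulin gene TUBA, named after its value was seen, rose on a shared probe set (log2 0.20 ± 0.05 SE). Its call held under 2 of the 4 other scalings.

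The fall of Hmgb3 was 3.61-fold, and its second probe set also gave -1.85. The histone genes H2A-9 and wcH2B-8 fell 1.73-fold and 1.63-fold on their brightest probe sets, with 2 of 3 and 2 of 4 probe sets lower. Of the 2 tested genes of the histone list H2A-9 fell, and H2A-3 was at log2 -0.21 ± 0.13 SE; wcH2B-8 lay outside the list's pattern, as did wcH2B-6, named after its value was seen (-0.36 ± 0.15 SE, no call). H2A-9 lost its call under quantile normalization (log2 -0.60) and cyclic loess (-0.58), and without control replicate 1 (-0.77), control replicate 2 (-0.81) or heat replicate 2 (-0.72). wcH2B-8 lost it in the same settings (-0.56, -0.53, -0.79, -0.62 and -0.45, in that order) and without shared probe sets (-0.37).

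Other falls reached about 2-fold. PR5, a thaumatin-like pathogenesis-related protein, fell 1.99-fold from 4511 ± 215 to 2271 ± 60.9 (SD, n = 2). It was 1 of 3 tested members of the defence list. The others were PER1, a peroxidase gene (log2 -0.70 ± 0.47 SE), and abu-7, a glutenin gene caught by the list's pattern. That pattern also named xylanase inhibitors, but the synonyms of xip did not match it, so its 2.85-fold rise is not counted there. No common direction of defence genes can be read from this list. PCS1, phytochelatin synthase of heavy metal detoxification, fell 1.96-fold. SAHH, adenosylhomocysteinase of the methyl cycle, fell 1.73-fold on a bright signal (15831 ± 471 to 9146 ± 307, SD, n = 2). The zinc finger gene WZF1 fell 1.96-fold, a call lost without control replicate 1 (log2 -0.74).

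**Figure D3:**
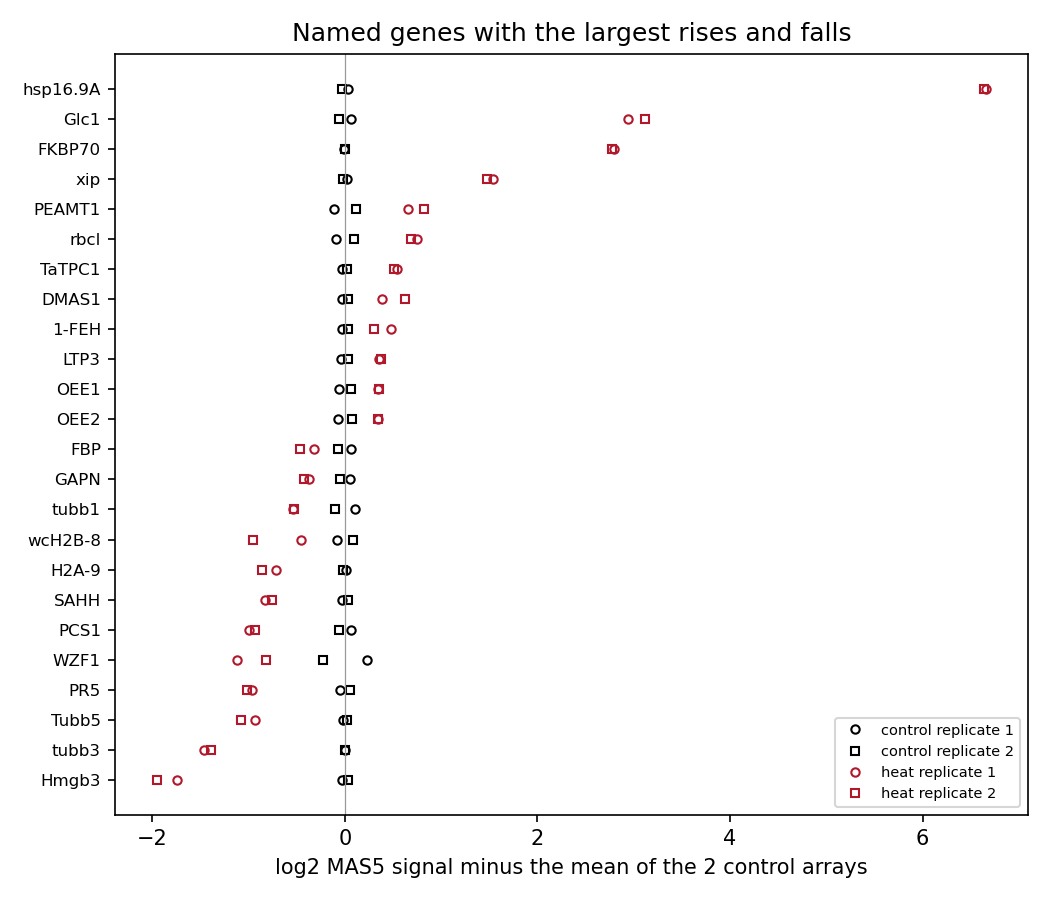
For the 12 named genes with the largest rise and the 12 with the largest fall, points give the log2 MAS5 signal of each array minus the mean of the 2 control arrays (x axis), black for control and red for heat, circles for replicate 1 and squares for replicate 2. The heat arrays of hsp16.9A lie near 6.65, and in no gene do the groups overlap, as the choice of these genes required.

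Of 4 tested antioxidant genes, catalase CAT1 rose 1.22-fold, GSTZ1 (a glutathione transferase) fell 1.15-fold, and Trx-M and Prx1 did not pass (log2 -0.08 and 0.08). Probe sets of a gene disagreed here, since the second of CAT1 stood at -0.43 with no call, 1 of the 4 of Prx1 was higher (0.67), and 2 of the 3 of GSTZ1 were lower. CAT1 lost its call under quantile normalization (log2 0.03) and cyclic loess (0.05). The value of GSTZ1 (log2 -0.20) lay close to the median over all tested probe sets (-0.15). By its signal, however, GSTZ1 is among the 6118 brightest, whose median was -0.027. It lost its call with median centring (-0.08), spike scaling (-0.13) or no filter, and without control replicate 2 (-0.15), heat replicate 1 (-0.19) or heat replicate 2 (-0.20), and stood at 0.02 without shared probe sets. Trx-M and H+-ATPase, a proton pump gene and the only tested member of the ion transport list (log2 -0.07), were lower past the threshold under quantile normalization (-0.38 and -0.42) and cyclic loess (-0.29 and -0.24), and above 0 with median centring (0.04 and 0.05).

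The translation initiation factor eIF-4E-1 rose 1.19-fold, 1 of 3 tested translation factors, with Eif4B at log2 0.15 and eIF-2-beta at 0.08. Of 2 tested ribosomal proteins, RPL9 (CL9) rose 1.18-fold and RPS29 was at log2 -0.34 ± 0.19 SE. The eIF-4E-1 and RPL9 calls were lost under quantile normalization (log2 0.21 and 0.20), with no filter, and without control replicate 1 (0.19 and 0.17), control replicate 2 (0.32 and 0.29) or heat replicate 2 (0.18 and 0.20). UBC1, a ubiquitin-conjugating enzyme and the only tested member of the ubiquitin list, was at log2 0.05, and lower past the threshold under quantile normalization (-0.27).

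Seed storage and grain proteins had been listed as markers of another organ. Of the 11 genes with a name, 4 were bright enough to test and 0 passed in limma, with 0 also at an unadjusted p below 0.05. The values were log2 -0.02 for ALP, -0.08 for Serpin-Z2A, 0.51 ± 0.42 SE for abu-7 and -0.26 ± 0.32 SE for the gliadin gene Prolamin. ALP, an avenin-like gene, had a signal of 7920 ± 77.9 in control and 7817 ± 130 in heat (SD, n = 2), and the group means of the other 3 lay between 125 and 283. With ALP this bright in both groups, the list gives no clean check for another organ.

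Beyond the 12 largest rises and 12 largest falls, the other 12 named genes that rose had log2 fold changes of 0.17 to 0.34 and the other 5 that fell of -0.36 to -0.20. Under all 4 other scalings, 11 of the 24 rises and 10 of the 17 falls still passed. Among the 45 genes named by the rule, eBayes without the intensity trend lost 16 calls at unchanged fold changes, those of DMAS1, 1-FEH, LTP3, PsbO, PsbP, AGP-S, CAT1, eIF-4E-1, RPL9, GSTZ1, Tubb4, FBP, GAPN, tubb1, wcH2B-8 and WZF1. Unmoderated t statistics lost these and the calls of PEAMT1, rbcL, H2A-9, PCS1 and Tubb5, 21 in all. These fits were not examined for the named genes outside the rule.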

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

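The fits with control probe sets were made after the data were seen. Control probe sets of the array stay outside the tested set, and 25 of them represent wheat genes named in their identifiers. When these were added to the limma fit, 7 were higher on the heat arrays at an adjusted p below 0.05 and 2, both for actin, were lower. Those that were higher are a signal outside the main measurement that lies above the control arrays.

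Sucrose synthase (Sucsyn) rose by log2 0.58 on its 3' probe set, from 11021 ± 137 to 16465 ± 481 (SD, n = 2), and by 0.81 on its middle probe set, while its 5' probe set was at 0.12. Ubiquitin, which marks proteins for degradation, was higher by 0.38, 0.28 and 0.25 on its 3', 5' and middle probe sets on the deposited scaling, but under quantile normalization these stood at 0.011, -0.045 and -0.076 with no call, and under cyclic loess only the 3' probe set passed (0.19, against 0.072 and 0.084). The 18S rRNA probe set was higher by 0.42, and by 0.16 under quantile normalization. The middle probe set of CYP86 was higher by 1.49, while its 5' probe set was at 0.12 and its 3' probe set at -0.43, neither past the threshold. Actin was lower on its 3' probe set (log2 -1.41) and its 5' probe set (-1.95; no call under quantile normalization or cyclic loess), but its middle probe sets were at 0.43 and 0.50 and did not pass. The calls of sucrose synthase, 18S rRNA, CYP86 and the actin 3' probe set held under quantile normalization, median centring, cyclic loess and spike scaling.

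Below the brightness filter, 168 of 30589 dim probe sets were higher and 194 were lower on the heat arrays in the limma fit without a filter.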

How the results depend on the processing

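Scaling on the polyA spike controls, leaving out the reporter controls, unmoderated t statistics for named genes and all scalings of control probe sets were chosen after the data were seen. The comparison called 11332 probe sets, 3793 of them changed at least 2-fold, with 38.3% of calls rises. The total was 6998 without shared probe sets, where fewer (21303) were tested. Unmoderated t statistics gave 2593 calls, 1364 with 2-fold changes and 49.2% rises. The stricter filter on dim probe sets left 15295 to test and 2027 calls with 2-fold changes. Median centring moved the share of rises to 50.4%. Leaving out 1 array at a time gave 7628 to 10665 calls, 3173 to 4147 with 2-fold changes and 36.2% to 45.4% rises; the lone array of a group is then assumed to vary like the others. With the replicate number as a block 11603 probe sets passed, and no call of a named gene or of the list changed. Same-numbered arrays did not deviate together (r = 0.0111 across probe sets). This single correlation cannot show whether they were paired, and the labels do not say what the number means. Without the reporter controls 11329 passed. All other alternatives kept these counts within 1.5 times. The cytoskeleton and cell wall list (median -0.44) did not pass limma's camera in the main fit (adjusted p = 0.13) or with an estimated correlation (adjusted p = 0.281). It passed limma's camera under quantile normalization (-0.41, adjusted p = 0.0175, with 1 list in the family) and without the filter (-0.44, adjusted p = 0.0304). It also passed limma's fry (-0.44, adjusted p = 0.0043), which does not compare it with other genes. Leaving out arrays gave -0.49 to -0.39 with no call. The list fell under the smallest size set for a test without shared probe sets and with the stricter filter, so it has no value there.

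Over 45 named genes and 789 gene-by-alternative values, 686 kept direction and side of the threshold, 76 lost the call, 6 gained one and 21 changed sign. Without shared probe sets rbcL (-0.67), DMAS1 (-0.23), UBC1 (-0.15) and GSTZ1 (0.017) changed sign. Quantile normalization turned PRK (-0.12), Prx1 (-0.029), UBC1 (-0.27) and Serpin-Z2A (0.095). Cyclic loess turned PRK (-0.10), UBC1 (-0.090) and Serpin-Z2A (0.12). Median centring turned ALP (0.099), H+-ATPase (0.046), Trx-M (0.041) and Serpin-Z2A (0.034), and spike scaling ALP (0.048). Leaving out arrays gave abu-7 -0.073 to 1.09, Serpin-Z2A -0.28 to 0.11, H+-ATPase -0.15 to 0.0065 and Prolamin -0.54 to 0.022. Except where fewer probe sets or arrays entered, the cause was not tested. Of the control probe sets, ubiquitin changed sign under quantile normalization on its 5' (-0.045) and middle (-0.076) probe sets. Dim signals limit the test. The median SE was 0.42 over the 6118 dimmest tested probe sets (188 higher, 389 lower) and 0.067 over the 6118 brightest (1908 higher, 2063 lower).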

Other observations

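Tests of the spike scaling, of 3'/5' ratios and of rbcL probe sets were chosen after the result was seen; the others were fixed before theirs. Of the 573 genes with a tested probe set, most of them known here only by a LOC number, 167 rose and 143 fell. Among the LOC numbers, chosen after their values were seen, LOC543477 rose 118-fold, from 234 ± 23.7 to 27576 ± 51.1 (SD, n = 2), and LOC542846 rose 59.6-fold to 31818 ± 527. LOC606310 fell (log2 -4.02), from 1255 ± 116 to 77.4 ± 8.91 (SD, n = 2), and LOC606312 fell (log2 -2.96), from 10571 ± 7 to 1359 ± 26.5. Probe sets that share a cluster number in their identifier mostly moved together. In 1605 of 1747 clusters with at least 2 called probe sets all went one way (91.9%), against 44.2% with directions shuffled.

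Changes of 16-fold or more were mostly rises (112 against 17). A signal floor was tested by holding both ends to the same level. Of the probe sets at 16 times the floor or more (a signal of 1105) on the heat arrays, 1.18% had risen 16-fold, against 0.12% at that level on the control arrays that fell 16-fold, a ratio of 9.88, where a floor would make the shares alike. Several probe sets per cluster name do not account for it either, since 94 cluster names rose and 16 fell (ratio 5.88). Gene copies and related transcripts under different cluster names could not be counted together, so repeats among those stay open. The scaling does not account for it, as the ratio was 9.17 to 11.5 under the other scalings. A candidate explanation is that 1 h allows new transcripts to accumulate many-fold while existing ones may decay only as fast as their half-lives permit; transcript half-lives were not measured, and the move to the chamber stays open beside heat.

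More probe sets fell than rose (6993 against 4339, median log2 -0.148). Scaling to a common trimmed mean could shift all others down where transcripts rose within the range that enters the mean. On the 36 probe sets of polyA spike controls, the median became -0.0806, with a 95% interval over arrays of -0.251 to 0.0901, which holds both 0 and the deposited value. The polyA spikes differed by a mean log2 of -0.0675 (heat minus control). The 27 probe sets of hybridisation controls, not used for scaling, differed the other way (0.0533). More 3' biased RNA on the heat arrays was tested on 5 wheat control transcripts, of which 2 had a higher 3'/5' ratio on both heat arrays, 2 had a lower one, and actin overlapped between groups. With so few arrays and transcripts, a broad fall in heat, the scaling and RNA quality cannot be told apart.

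Probe sets assigned to rbcL went both ways: the 2 brightest rose (0.72 and 0.58) and 7 dimmer ones fell, down to -2.08. A general fall of dim probe sets does not account for the 3 that fell in the brightest of 5 classes. There the 95% intervals of all 5 rbcL probe sets exclude the median of that class (-0.0268), 2 above and 3 below it. The class spans signals of 1652 to 55380, so its median is a coarse reference for the 2 that rose, at 46710 and 31190. Of the 7 rbcL probe sets below the brightest class, called or not, 4 intervals lie below the median of their class and 3 hold it. The median of these 7 was log2 -0.872, against -0.173 for 10000 random sets matched on brightness. Only 0.85% of the random sets lay as low, which argues against a general fall of dim probe sets for these 7 as a set. Probe sets of 1 gene are not independent, whereas the random ones were drawn independently. Dim probe sets that report other transcripts may be the source; over the 12 probe sets the correlation of fold change with signal was rho = 0.476 (permutation p = 0.121), which leaves this open. The labelling of plastid transcripts was not tested.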
